A study of Mus musculus with 12 samples.

How the data were processed

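RNA was sequenced from proximal and distal small intestine of WT and Bmpr1a cKO mice, with 3 libraries in each of the 4 groups. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Ovation RNA-Seq System V2 kit. Per the submitters' processing notes, reads were aligned to mm10 with STAR (version not given in the sources used here) and analysed with DESeq2 1.28.1. The analysis started from the table of 17175 genes that the authors deposited, and raw reads were not analysed here. All 12 columns of sample values were matched to a sample by their names, with 0 columns left over. Of the gene identifiers, 17158 were found in GENCODE M21 and 16998 carried the symbol given there.

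The deposited sample values are a signal scaled per library. Every one of the 206100 deposited values was a whole multiple of a step specific to its column, within 0.001 steps, and 10499 values stood at exactly 1 step, so each was taken as (read count + 1) divided by a size factor. Whole reads were recovered by dividing by the step and subtracting 1. The deposited log2 fold change was found by arithmetic to be that of cKO proximal over WT distal libraries (median absolute difference 0.0017, against 0.395 for the next closest pair of groups), a contrast in which genotype and segment change together. The deposited standard error of that log2 fold change and the deposited Wald statistic, a score, belong to the same contrast. A DESeq2 1.42.0 fit of the recovered reads + 1 matched the deposited score with r = 1 and a median absolute difference of 0.000303. The deposited p-value of each gene is from that Wald test, and the deposited adjusted p-value equals the Benjamini-Hochberg adjustment over the genes given, to within 1.4e-15. In the table deposited by the authors, 6821 genes had an adjusted p-value under 0.05, 3661 higher and 3160 lower. This contrast was not used further.

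The choice of tests was made before the data were examined and assumed read counts. As the table held scaled values instead, the test set for that case was used: limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) on log2(value + 1), with 4 group means and all 12 libraries in one fit, and Benjamini-Hochberg adjusted p under 0.05. The filter (a value of at least 1 in 3 or more libraries) removed 0 genes. It could hardly remove any, since a gene with 0 reads has a value of 1 divided by the size factor, which lay below 1 in 10 of the 12 libraries. The table had been filtered before deposit by a rule not given in the sources used here. Fold changes of genes with few reads are understated on this scale. The comparisons were cKO against WT in each segment, distal against proximal in each genotype, and the difference of the genotype effects (the interaction). The genotype effect averaged over segments was also compared with the segment effect averaged over genotypes, with an exact permutation over the 6 numbered sample pairs.

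Depth was 11242024 to 17722756 recovered reads per library. A group at 0 reads in all 3 libraries was compared against a floor of 3 reads per library, and its fold change is given as a lower bound. Such a value occurred for 670 genes in at least 1 group, and 3237 genes had 0 reads in at least 1 library.

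The genes named follow a rule fixed before the data were examined. Named in each comparison were (a) Bmpr1a; (b) the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among genes past the threshold, with a mean log2 CPM of at least 2 and no overlap between the libraries of the 2 groups (not required for the interaction), leaving out predicted and clone-named genes; (c) up to 4 members with the smallest p from each list described, passing members first; and (d) in the genotype comparisons, the 4 members of the BMP-induced and Wnt target lists with the smallest p. Genes named outside the rule are said to be, and a few genes that the rule names are not reported here.

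Gene groups were 37 lists of up to 48 measured genes, written before the data were examined. They covered signalling pathways, epithelial cell types, enterocyte functions, the proximal to distal axis, metabolism, and markers of other cell types and of handling. Each list was tested with camera (preset correlation 0.01) on the same fit, adjusted over the lists. The same test was run with a correlation estimated per list, and no list passed that form in any comparison. A count adjusted over the list alone uses the p-values of the list's own genes.

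Libraries carry the numbers 1 to 3 in each group. Whether the numbers pair the samples was checked before the fits were compared, by correlating the deviations of libraries from their group means. Between segments of a genotype, libraries of one number correlated at 0.31, 0.17 and 0.31 in WT and at 0.16, 0.21 and 0.32 in cKO, and 12 of 12 libraries correlated best with their own number. The sample names in the labels (WT1, KO1 and so on) are shared between segments too. The numbers were therefore taken to pair the samples of the 2 segments, and a fit with the genotype and number as a block was run for segment comparisons and the interaction.

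The tests were tried on simulated data with 17175 genes, of which 100 changed 2-fold and 100 changed 4-fold, in the spread of these libraries. In the proximal genotype comparison limma recovered 26 and 79 of them with 5.41% false calls, in the distal one 38 and 86 with 6.77%, in the segment comparisons 31 and 79 (WT, 4.35%) and 40 and 85 (cKO, 6.72%), and in the interaction 3 and 55 with 4.92%. DESeq2 gave 16.5 to 22.7% false calls on the same data. Camera found the 1 list changed in each of the 5 comparisons and none of the 36 others, with the preset and with the estimated correlation alike. The simulated genes varied independently of each other, so this trial could not test camera on lists whose genes vary together. The estimated correlation in the real data was, for example, 0.81 for the T cell and intraepithelial lymphocyte list.

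Alternatives fixed beforehand were pseudocounts of 0.1 and 5, a 2-fold threshold, a fit of only the 6 libraries compared, the sample number as a block, leaving out each library in turn, edgeR 4.0.16 with DESeq2 size factors, without a low count filter and with a stricter one, limma voom, the DESeq2 Wald test, and for lists the estimated correlation and the fry test. Chosen after seeing the data were edgeR on recovered reads with TMM factors, TMM factors in the limma fit, the mitochondrial read share as a covariate, and leaving out both cKO libraries numbered 1. Other divisions of the same libraries were fitted to see how many genes they call.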

Results

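RNA was sequenced from the small intestine of wild-type (WT) mice and of mice labelled Bmpr1a cKO, each at a proximal and a distal segment. Bmpr1a encodes a type I receptor for bone morphogenetic proteins (BMPs), and a cKO is a conditional knockout. The series description states the purpose as testing how BMP signals in epithelial cells relate to villus length along the intestine, and its title adds the crosstalk with Wnt signalling. Each of the 4 groups held 3 libraries, 12 in all. The deposited table covered 17175 genes, with 11242024 to 16381314 recovered reads per WT library and 15225731 to 17722756 per cKO library. The labels do not state that libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be in part technical. Values are scaled read counts, given as mean ± SD with n = 3 per group.

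The libraries fell apart by group. The first principal component, with 39.1% of the variance, placed the WT distal libraries at 82.2 to 112.6, away from the other 9 libraries. The second, with 26.2%, ran from the WT proximal libraries (57.2 to 71.2) to the cKO distal libraries (-84.4 to -69). Reads from mitochondrially encoded genes took 22.8 ± 4.68% of the WT proximal libraries, 29.8 ± 7.71% of the WT distal, 12 ± 2.59% of the cKO proximal and 16.4 ± 9.83% of the cKO distal libraries, where library 3 stood at 27.7%. Genotype accounted for 54.3% of the variance of this share on the log scale. Both cKO libraries numbered 1 held 0 reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, and each of the other libraries held reads of all 4.

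Bmpr1a itself showed no detectable difference between genotypes at the level of the whole gene. The gene lies on chromosome 14 from 34410734 to 34503341, minus strand, in mm10. Its scaled count was 943 ± 130 in cKO and 940 ± 146 in WT proximal libraries (log2 fold change 0.01, SE 0.19, limma adjusted p = 0.983). In the distal segment it was 555 ± 98.7 in cKO and 532 ± 96.6 in WT (log2 fold change 0.06, SE 0.19, adjusted p = 0.852). A gene-level count includes exons outside any deleted part, so these values check neither the deletion nor the labels. The BMP-induced genes Id1 and Smad6 were lower in each of the 6 cKO libraries than in any WT library: Id1 stood at 112 to 232 in cKO and at 972 to 1650 in WT libraries, and Smad6 at 3.73 to 25.5 against 181 to 479.

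**Figure D1:**
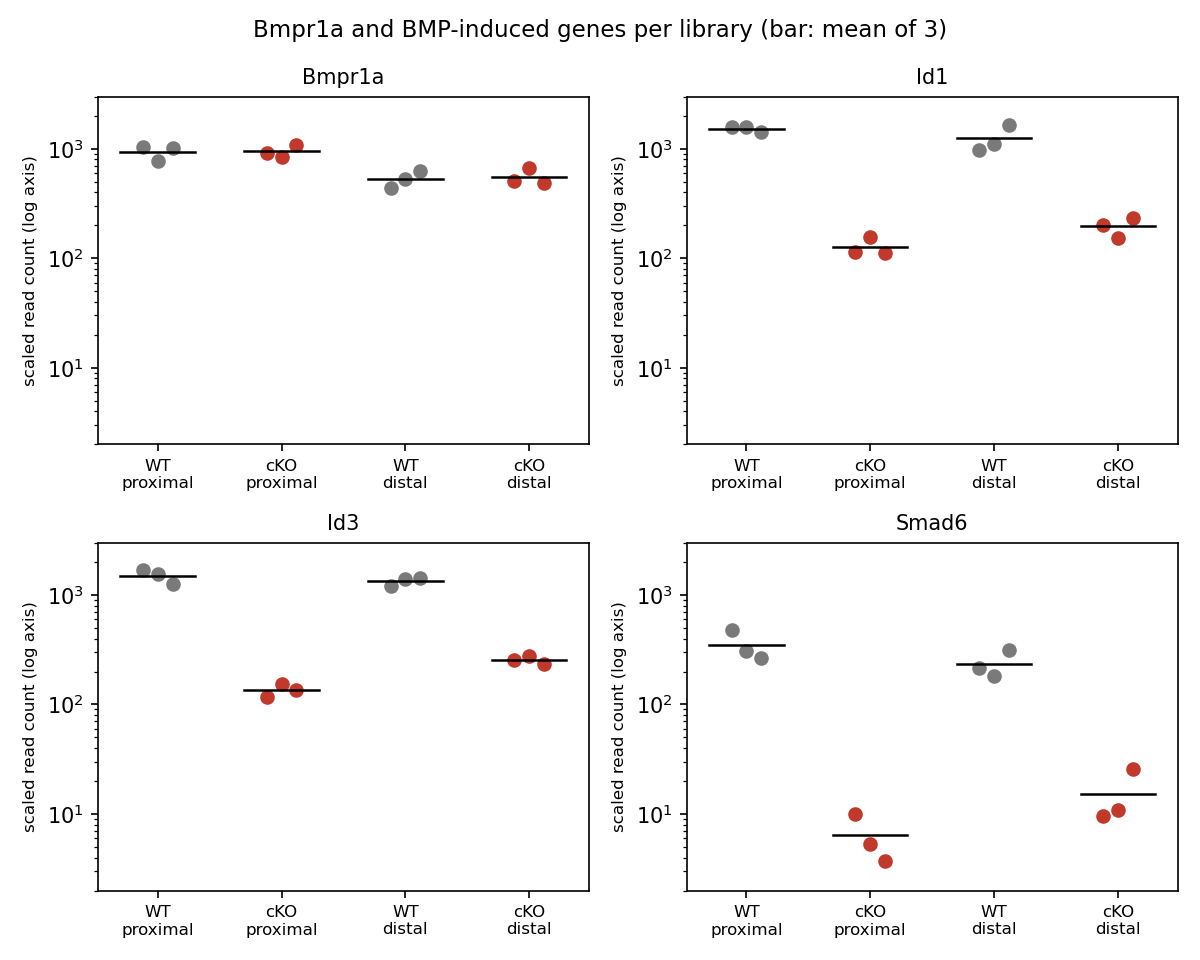
Scaled read counts (log axis) of Bmpr1a and of the BMP-induced genes Id1, Id3 and Smad6 in the 12 libraries, with a point per library and a bar at the mean of the 3 libraries of a group. Bmpr1a overlaps between genotypes in both segments, while Id1, Id3 and Smad6 of the cKO libraries lie below those of all WT libraries.

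The first comparison asked what differed in the proximal segment between cKO and WT. Among BMP-induced genes, Id3 dropped from 1500 ± 215 to 136 ± 19.3 and Id1 from 1520 ± 97.2 to 127 ± 25, both inhibitors of DNA-binding transcription factors. The inhibitory SMAD gene Smad6 dropped from 351 ± 113 to 6.37 ± 3.32 (log2 fold changes of Id3, Id1 and Smad6 -3.45, -3.59 and -5.62, adjusted p = 1.48e-07, 9.15e-07 and 6.14e-06). Reg3b, a bactericidal lectin, rose from 3800 ± 1350 to 76600 ± 24300. The hormone genes Pyy (peptide YY) and Sct (secretin) fell, from 235 ± 45.4 to 3.55 ± 2.57 and from 1710 ± 529 to 113 ± 34.1. Among markers of immune cells, Jchain of plasma cells and C1qa of macrophages fell.

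In the proximal segment 1418 genes passed (limma, adjusted p under 0.05), 723 higher and 695 lower in cKO. Of these, 1084 changed at least 2-fold, 428 higher and 656 lower. By the naming rule the largest increases besides Reg3b were in Eno1b (8.02, SE 0.41), Mbl2, a mannose-binding lectin (6.08, SE 0.49), Bmp3, a BMP family ligand (5.72, SE 0.56), Trim46 (4.98, SE 0.45) and the water channel gene Aqp4 (3.6, SE 0.48), all as log2 fold changes. Mbl2 (chromosome 19, 30232942 to 30239687) went from 27.3 ± 7.1 to 2130 ± 1130, and Bmp3 (chromosome 5, 98854415 to 98884396) from 56.7 ± 38.2 to 2520 ± 738. Eno1b (chromosome 18, 48045335 to 48048412) went from 8.68 ± 1.31 to 2500 ± 198, but its transcript is 99.5% identical to that of Eno1 over 1652 bases, so its reads are uncertain. The largest decreases by that rule besides Pyy, Sct, Id1 and Id3 were in Adamdec1, a metalloprotease gene of the lamina propria (-6.31, SE 0.64), and in the immunoglobulin constant gene Ighg1 (-3.03, SE 0.67, adjusted p = 0.0161), which shares sequence with other heavy chain genes. The Ighg1 call ended without WT proximal 3, cKO proximal 1 or cKO proximal 3 (highest adjusted p = 0.0644). Rescaling by trimmed mean of M-values (TMM) moved the median over all genes from 0.084 to -0.028 and the higher share of calls from 51% to 39.7% (1428 genes). Over all fits without a fold threshold that share lay between 39.7% and 57.4%. The count also moved to 292 with the mitochondrial share as a covariate, to 2322 in DESeq2, to 766 without both cKO libraries numbered 1, and to 587, 694, 810, 580 and 687 without WT proximal 2, WT proximal 3, cKO proximal 1, cKO proximal 2 and cKO proximal 3.

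Of 7 signalling lists 2 passed in the proximal segment, the BMP-induced and the Wnt target genes. Of 11 measured BMP-induced genes 6 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (median log2 fold change -1.5, camera adjusted p = 1.62e-07, and adjusted p = 0.062 with an estimated correlation). Besides Id1, Id3 and Smad6, Smad7 fell from 937 ± 213 to 362 ± 17.8. The member that rose, Hes1 (0.89, adjusted p = 0.0462), is also a Notch target, and its call ended when any of the 6 libraries was left out (highest adjusted p = 0.151). Of 19 Wnt target genes 4 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (median -0.87, camera adjusted p = 0.000213, and adjusted p = 0.153 with an estimated correlation). Axin2, a feedback inhibitor of Wnt signalling, fell from 291 ± 83.9 to 52.9 ± 5.99, and Tnfrsf19 had 0 reads in the cKO proximal libraries, at least 2.06-fold lower than in WT against a floor of 3 reads per library. Ephb2, a receptor for ephrin-B ligands, rose from 148 ± 36.2 to 478 ± 89.9. Prox1 fell (-1.63, adjusted p = 0.0188), a call that ended without WT proximal 1 or cKO proximal 2 (highest adjusted p = 0.0833).

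Among epithelial groups of the proximal segment, the villus base antimicrobial genes rose, while the Paneth cell list, which holds defensins, had a median of -0.97 (camera adjusted p = 0.0135, and adjusted p = 0.753 with an estimated correlation). Of its 17 genes 1 rose and 1 fell over all genes and adjusted over the list alone, and the call ended without WT proximal 3 (0.103) and with the mitochondrial share as a covariate (0.642). Of 15 measured villus base members 8 rose and 0 fell, and 9 rose adjusted over the list alone (median 1.48, camera adjusted p = 6.64e-06, and adjusted p = 0.5 with an estimated correlation). Duox2 and Duoxa2, the oxidase and its maturation factor, went from 35.3 ± 24.1 to 376 ± 183 and from 8.66 ± 4.66 to 66.5 ± 31.4, and Lypd8, which binds flagellated bacteria, from 15600 ± 4540 to 93200 ± 20600. Reg family genes share sequence, so the division of reads between Reg3b and its relatives is uncertain. Enteroendocrine genes fell: 8 of 27 fell and 1 rose, and 9 fell and 2 rose adjusted over the list alone (median -0.58, camera adjusted p = 0.000106, and adjusted p = 0.578 with an estimated correlation). Tph1, the enzyme of serotonin synthesis, fell from 925 ± 210 to 130 ± 86.6 and the neurotensin gene Nts from 147 ± 81.9 to 19.5 ± 3.71. Of 22 tuft cell genes 4 fell, and 11 fell adjusted over the list alone (median -1.37, camera adjusted p = 1.04e-06, and adjusted p = 0.578 with an estimated correlation). The call of Ptgs1 ended without cKO proximal 2 (adjusted p = 0.0645) and those of Matk and Gnat3 without any of the 6 libraries (highest adjusted p = 0.145 and 0.152). Cholesterol synthesis genes rose, 8 of 21, and 19 of 21 adjusted over the list alone (median 0.82, camera adjusted p = 7.72e-09, and adjusted p = 0.5 with an estimated correlation). Examples were Idi1 (1.39) and Cyp51 (1.34). By the fry test the villus base and cholesterol synthesis lists passed (fry adjusted p = 0.0343 and 0.0302). The Paneth cell, enteroendocrine and tuft cell lists did not (fry adjusted p = 0.442, 0.0937 and 0.198). The cell cycle list did not pass (median -0.03, camera adjusted p = 0.431).

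Of 10 lists of other cell types 4 passed in the proximal segment, all lower in cKO (camera, and adjusted p = 0.5 to 0.578 with an estimated correlation). Those of smooth muscle, endothelium, enteric neurons and glia, pancreatic acinar cells, stomach and Brunner gland, and erythrocytes did not (camera adjusted p = 0.149, 0.0568, 0.752, 0.228, 0.724 and 0.286). Of 15 B cell and plasma cell genes 9 fell, and 12 adjusted over the list alone (median -2.13, camera adjusted p = 2.58e-08, and adjusted p = 0.5 with an estimated correlation), among them Jchain, from 1480 ± 516 to 294 ± 213. Of 16 myeloid genes 7 fell, and 10 adjusted over the list alone (median -1.4, camera adjusted p = 2.58e-08, and adjusted p = 0.5 with an estimated correlation), and C1qa, a complement gene of macrophages, fell from 1480 ± 459 to 273 ± 90.9. In the fibroblast and telocyte list 1 of 19 genes fell over all genes and adjusted over the list alone (Postn, -2.67), with a list median of -1.44 (camera adjusted p = 1.51e-05, and adjusted p = 0.578 with an estimated correlation). In the T cell and intraepithelial lymphocyte list 1 of 17 fell, and 3 adjusted over the list alone (median -0.92, camera adjusted p = 1.02e-05, and adjusted p = 0.578 with an estimated correlation). The fibroblast and T cell lists did not pass by fry (fry adjusted p = 0.198 and 0.217), while the B cell and myeloid lists did (0.0462 for each). The T cell list level (mean centred log2 value) of cKO proximal 1 (1.13) lay above that of WT proximal 1 (0.65). Mitochondrially encoded mRNA had a median of -1.04, with 2 of 12 genes passing over all genes and adjusted over the list alone (camera adjusted p = 3.43e-06, and adjusted p = 0.578 with an estimated correlation). That list did not pass by fry (fry adjusted p = 0.104).

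The second comparison asked the same question in the distal segment. Among BMP-induced genes Id3 fell there too, from 1340 ± 120 to 255 ± 23, Id1 from 1250 ± 357 to 195 ± 40.4 and Smad6 from 236 ± 68.2 to 15.3 ± 8.89. Of genes typical of proximal enterocytes, Fabp1, a fatty acid binding protein, rose from 1700 ± 152 to 8810 ± 3540 and Treh, the trehalase of the brush border, from 1410 ± 1080 to 11900 ± 5150. The cell cycle gene Mcm5, a replication helicase subunit, fell from 776 ± 89.3 to 244 ± 83.6. Of B cell genes, Ighg2b went from 8200 ± 2450 to 19.3 ± 10.9 and Ms4a1, which encodes CD20, from 1980 ± 910 to 35.7 ± 20.6.

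In the distal segment 4297 genes passed (limma, adjusted p under 0.05), 2279 higher and 2018 lower in cKO. Of these, 2941 changed at least 2-fold, 1158 higher and 1783 lower. By the naming rule the largest increases besides Eno1b (8.13) were in Mbl2 (4.86, SE 0.49), Bmp3 (3.95, SE 0.56), Bbox1, an enzyme of carnitine synthesis (3.78, SE 0.49), the membrane carbonic anhydrase gene Car4 (3.6, SE 0.76) and the tissue factor gene F3 (3.56, SE 0.39). Car4 went from 676 ± 254 to 9310 ± 6470 and F3 from 26.8 ± 15.8 to 295 ± 42. Large decreases by that rule were in B cell genes: Ighg2b (-8.77, SE 0.58), Ms4a1 (-5.79, SE 0.59), the transcription factor gene Pax5 (-5.73, SE 0.7), Tnfrsf13c (-5.62, SE 0.56) and Pou2af1 (-5.62, SE 0.49). The count moved to 1356 with the mitochondrial share as a covariate (31.3% of the calls higher, against 53%) and to 2160 without both cKO libraries numbered 1 (39.1% higher). It was 2672 without WT distal 2 and 2466 without cKO distal 1, and 3106 without WT distal 1 (42.1% higher). The higher share was 48.2% with TMM factors, 44.3% with voom weights and 49.6% in DESeq2, so which direction held more calls depended on the fit.

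Of 48 proximal enterocyte genes 33 rose and 1 fell in the distal segment, and 37 rose and 1 fell adjusted over the list alone (median 1.41, camera adjusted p = 5.83e-12, and adjusted p = 0.647 with an estimated correlation). The glutathione transferase gene Gstm6 rose from 80.8 ± 22.2 to 408 ± 109, the retinaldehyde dehydrogenase gene Aldh1a1 from 1700 ± 241 to 6290 ± 838 and Hsd17b6 from 195 ± 45.3 to 1560 ± 649. The member that fell was Slc40a1, the iron exporter ferroportin (from 578 ± 47.2 to 59.5 ± 20.2, log2 fold change -3.32, adjusted p = 4.63e-06). Distal enterocyte genes also rose, 12 of 38 over all genes and adjusted over the list alone, with 0 lower (median 0.69, camera adjusted p = 0.00162, and adjusted p = 0.671 with an estimated correlation). Examples were the aminopeptidase gene Enpep, from 14100 ± 9450 to 45700 ± 17800, and the efflux pump gene Abcb1a, from 6610 ± 6020 to 22500 ± 5820. The mean level of the distal enterocyte list changed by 0.74 (SE 0.42), and the list did not pass by fry (fry adjusted p = 0.135). Its level (mean centred log2 value) in WT distal 3 (1.67) lay above that in cKO distal 3 (1.32). The camera call of this list was lost with the mitochondrial share as a covariate (camera adjusted p = 0.481), as were those of the brush border, Paneth cell, myeloid and mitochondrially encoded lists of this segment (0.998, 0.761, 0.338 and 0.86). The mitochondrial reads were lower beside these groups: the mitochondrially encoded list had a median of -0.88, with 2 of 12 genes lower over all genes and adjusted over the list alone (camera adjusted p = 0.00251, and adjusted p = 0.659 with an estimated correlation).

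Of 5 metabolic lists 4 rose in the distal segment. In the sugar and peptide list 20 of 26 genes rose and 0 fell, and 24 rose adjusted over the list alone (median 1.59, camera adjusted p = 9.26e-09, and adjusted p = 0.647 with an estimated correlation). Slc2a5, the fructose transporter, rose from 946 ± 635 to 3510 ± 1340. For fat absorption and lipoprotein assembly 16 of 27 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (median 1.36, camera adjusted p = 1.46e-06, and adjusted p = 0.647 with an estimated correlation). Mttp, the lipid transfer protein that loads apolipoprotein B, rose from 9540 ± 5210 to 49200 ± 22200 and Apoc2 from 662 ± 45.1 to 2380 ± 562. The fatty acid oxidation and ketogenesis list had 13 of 26 higher and 1 lower, and 15 higher and 1 lower adjusted over the list alone (median 0.65, camera adjusted p = 0.000206, and adjusted p = 0.647 with an estimated correlation). Pdk4 rose from 20.8 ± 1.22 to 111 ± 52.6. Cholesterol synthesis genes rose, 11 of 21, and 14 adjusted over the list alone (median 0.76, camera adjusted p = 3.37e-05, and adjusted p = 0.659 with an estimated correlation).

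Cell cycle genes were lower in the distal cKO libraries, 23 of 38, and 25 adjusted over the list alone, with 0 higher (median -1.05, camera adjusted p = 1.45e-10, and adjusted p = 0.647 with an estimated correlation). Uhrf1 fell from 617 ± 102 to 190 ± 60.2 and Mcm3 from 701 ± 124 to 195 ± 78.9. Beside them, B cell and plasma cell genes fell, 14 of 15, and 15 adjusted over the list alone (median -5.21, camera adjusted p = 1.09e-13, and adjusted p = 0.426 with an estimated correlation). Mzb1, of the plasma cell endoplasmic reticulum, fell from 620 ± 128 to 15.7 ± 6.23 and Ighm from 6510 ± 2950 to 204 ± 98.2. Of 9 MHC class II genes 3 fell over all genes and adjusted over the list alone (median -1.38, camera adjusted p = 0.00555, and adjusted p = 0.659 with an estimated correlation). These were H2-Ob (-5.49), H2-Oa (-4.55) and the transactivator gene Ciita (-2.89), and the list call ended without cKO distal 3 (camera adjusted p = 0.0556). The other 6 members did not pass. The list level (mean centred log2 value) was 0.87, -0.96 and -1.54 in cKO distal 1 to 3, and 1.05, 2.13 and 1.78 in WT distal 1 to 3. Whether the MHC class II genes fell along with the B cell genes was not tested. Of 16 myeloid genes 5 fell over all genes and adjusted over the list alone (median -0.88, camera adjusted p = 0.0011, and adjusted p = 0.659 with an estimated correlation), a call that ended without WT distal 1 (camera adjusted p = 0.0855) and with the mitochondrial share (camera adjusted p = 0.338). Neither the MHC class II nor the myeloid list passed by fry (fry adjusted p = 0.0639 and 0.115). The fibroblast and telocyte list did not pass in this segment (median -0.63, camera adjusted p = 0.235).

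Of 11 BMP-induced genes 6 fell and 2 rose in the distal segment, over all genes and adjusted over the list alone (median -1.15, camera adjusted p = 0.00162, and adjusted p = 0.426 with an estimated correlation). Id2 fell from 525 ± 65.7 to 171 ± 47. The members that rose, Id4 (1.38, adjusted p = 0.0217) and Hes1 (0.76, adjusted p = 0.0429), were chosen after their values were seen. Wnt target genes did not pass as a list here (median -0.3, camera adjusted p = 0.129), with 5 of 19 lower and 1 higher, and 5 lower and 2 higher adjusted over the list alone. Among them Lef1 fell from 46.6 ± 9 to 5.94 ± 4.92, Tcf7 from 538 ± 184 to 69.4 ± 25.2 and Axin2 from 530 ± 124 to 159 ± 101, while Ephb2 rose from 200 ± 39.6 to 664 ± 41. Lef1 and Tcf7 encode transcription factors of Wnt signalling that lymphocytes also express. Goblet cell genes rose, 4 of 18, and 10 adjusted over the list alone (median 0.72, camera adjusted p = 0.00183, and adjusted p = 0.659 with an estimated correlation). Spink4 went from 3200 ± 908 to 10500 ± 3080, and the list call ended without cKO distal 3 (camera adjusted p = 0.0556). Tuft cell genes fell, 7 of 22 over all genes and adjusted over the list alone (median -1.18, camera adjusted p = 0.00143, and adjusted p = 0.671 with an estimated correlation), a call that ended without WT distal 1 (camera adjusted p = 0.217). Rgs13 went from 431 ± 244 to 112 ± 57.7 and the taste transducin gene Gnat3 from 47.1 ± 38.5 to 5.67 ± 1.64. Neither the goblet cell nor the tuft cell list passed by fry (fry adjusted p = 0.0892 and 0.167).

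**Figure D2:**
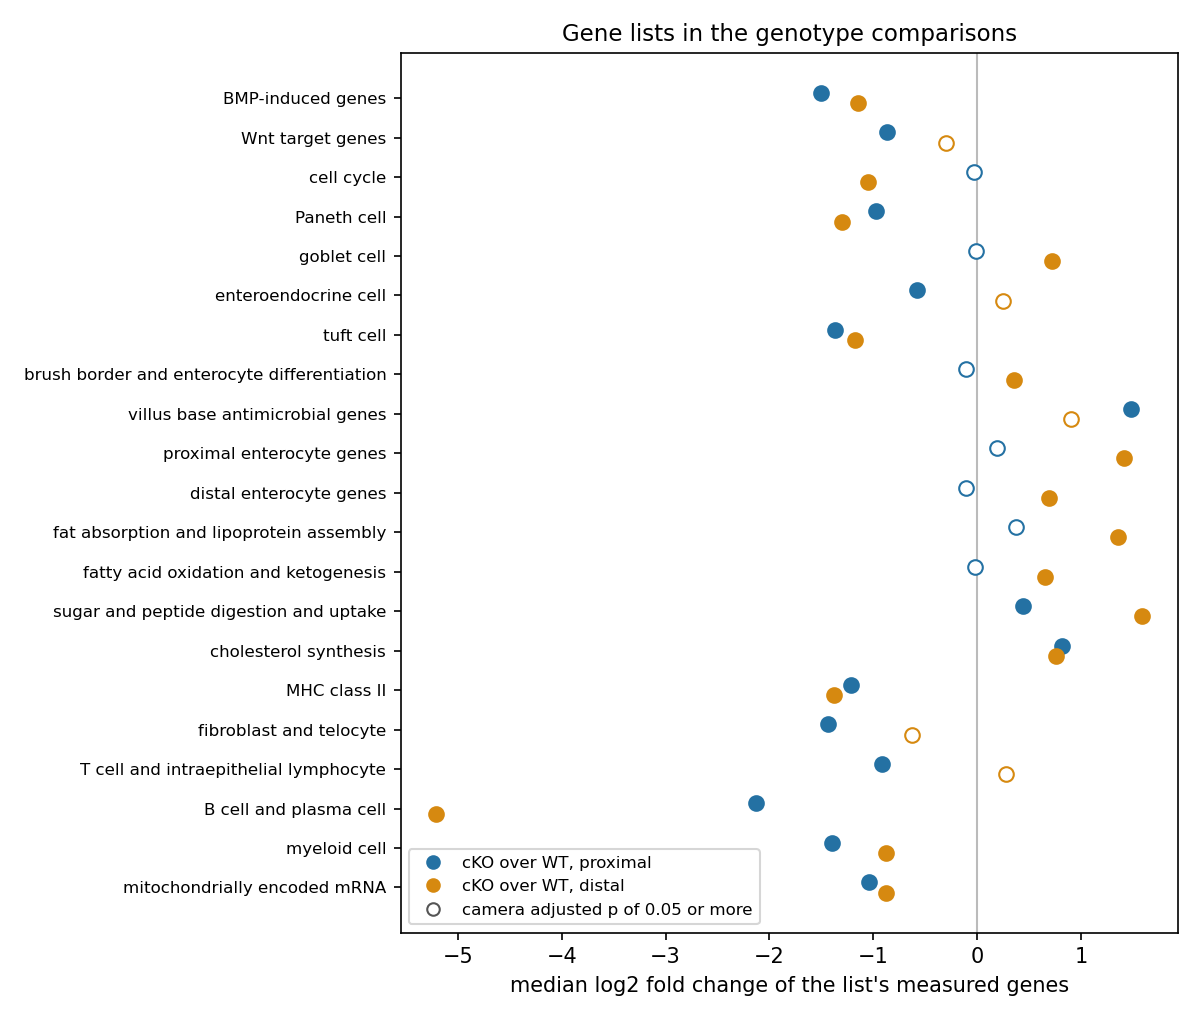
Median log2 fold change of cKO over WT for 21 gene lists (horizontal axis), in the proximal (blue) and distal (orange) segment. Filled points passed the camera test at an adjusted p under 0.05 and open points did not. BMP-induced genes lie at -1.5 and -1.15, proximal enterocyte genes at 0.19 and 1.41, and B cell and plasma cell genes at -2.13 and -5.21.

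The genotype effects of the 2 segments were compared gene by gene. BMP-induced Id1, Id3 and Smad6, and Mbl2, Bmp3 and Ephb2, changed the same way in both segments. Of the genes called in both, 451 were higher and 477 lower in both, where independent lists of these sizes would share 95.94 and 81.66. Another 6 were called in opposite directions: Xylt1, Mfge8, Blnk, Tmsb10 and 2610301B20Rik were higher in proximal and lower in distal cKO libraries, and Acsl6 was lower in proximal (-2.29) and higher in distal (1.85). These 6 are named after their values were seen. Mfge8, which marks apoptotic cells for uptake, was 1070 ± 349 in cKO and 264 ± 84.8 in WT proximal libraries, and 302 ± 130 against 740 ± 196 in distal ones. Across genes, which are not independent replicates, the log2 fold changes of the segments correlated at r = 0.651. Libraries of the same number share deviations between segments, so part of this could be carried by the samples. Over the other 9 ways of dividing the 6 numbered sample pairs into groups of 3, r had a median of 0.418 and reached 0.515. The covariance was 0.546 for the real division and at most 0.151 for the others. The genotypes are unevenly split in each of the other divisions, which therefore keep part of the genotype effect. They give no baseline free of it. The count of 928 genes called the same way moved to 135 with the mitochondrial share as a covariate, 460 without both cKO libraries numbered 1 and 1545 in DESeq2. It was 401, 439, 576, 398 and 487 without WT proximal 2, WT proximal 3, cKO proximal 1, cKO proximal 2 and cKO proximal 3.

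The third comparison described the proximal to distal difference in WT. Among genes higher in distal libraries were Slc10a2, the apical bile acid transporter (from 14.1 ± 6.71 to 2720 ± 1260), Fabp6, which binds bile acids in the cell (from 241 ± 341 to 31000 ± 13000), and Defa21 (from 37 ± 26.2 to 7730 ± 5520). Among genes lower in distal were the alkaline phosphatase gene Akp3 (from 163000 ± 27800 to 483 ± 798), the enteropeptidase gene Tmprss15 (from 4520 ± 1260 to 9.66 ± 14.8) and the transcription factor gene Pdx1 (from 1260 ± 347 to 10.2 ± 12.7). In all, 4137 genes passed (limma, adjusted p under 0.05), 2037 higher and 2100 lower in distal, 2786 of them by at least 2-fold (1431 higher, 1355 lower), and the count was 2741 without WT distal 2. This fit left the pairing out, and 4935 genes passed with the sample number as a block. Bmpr1a was 532 ± 96.6 in distal and 940 ± 146 in proximal WT libraries (-0.82, SE 0.19, adjusted p = 0.00718).

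The largest WT differences by the naming rule also included Plb1, a brush border phospholipase (8.86, SE 0.78), the monocarboxylate transporter gene Slc5a8 (7.86, SE 0.42) and Defa22 (7.67, SE 0.91) among genes higher in distal. Among those lower in distal they included Sult6b2 (-9.09, SE 0.99), Reg1 (-8.47, SE 0.78) and the proton channel gene Otop3 (-8.19, SE 0.59). Defensin genes are near-identical copies of each other and the division of their reads is uncertain. Of 48 proximal enterocyte genes 46 were lower in distal, and 47 adjusted over the list alone (median -2.78, camera adjusted p = 1.06e-34, and adjusted p = 0.301 with an estimated correlation). The bile acid list did not pass in WT, with 4 of 13 genes higher and 3 lower over all genes and adjusted over the list alone (median 0.68, camera adjusted p = 0.301, and adjusted p = 0.749 with an estimated correlation). Of 38 distal enterocyte genes 20 were higher and 1 lower over all genes and adjusted over the list alone (median 1.04, camera adjusted p = 2.58e-08, and adjusted p = 0.497 with an estimated correlation). Cell cycle genes were higher, 35 of 38, and 37 adjusted over the list alone (median 1.68, camera adjusted p = 3.27e-19, and adjusted p = 0.485 with an estimated correlation), for example Top2a from 273 ± 49.5 to 1180 ± 167. Paneth cell genes were higher, 10 of 17, and 15 adjusted over the list alone (median 2.4, camera adjusted p = 3.65e-06, and adjusted p = 0.497 with an estimated correlation). Enteroendocrine genes were lower, 18 of 27 with 1 higher, and 19 lower and 2 higher adjusted over the list alone (median -1.5, camera adjusted p = 1.31e-08, and adjusted p = 0.485 with an estimated correlation). Cck fell from 2760 ± 1230 to 74.3 ± 4.38 and Gip from 3700 ± 908 to 347 ± 69.7, while Nts rose from 147 ± 81.9 to 1030 ± 174.

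Fatty acid oxidation genes were lower in distal, 19 of 26 with 1 higher, and 22 lower and 1 higher adjusted over the list alone (median -1.12, camera adjusted p = 3.63e-11, and adjusted p = 0.301 with an estimated correlation). Pdk4 went from 676 ± 119 to 20.8 ± 1.22. Fat absorption genes were lower, 13 of 27 over all genes and adjusted over the list alone (median -0.78, camera adjusted p = 6.3e-08, and adjusted p = 0.485 with an estimated correlation), with Apoc2 going from 20200 ± 9260 to 662 ± 45.1. The sugar and peptide list had 11 of 26 lower and 2 higher, and 13 lower and 2 higher adjusted over the list alone (median -1.01, camera adjusted p = 0.00106, and adjusted p = 0.747 with an estimated correlation). Cholesterol synthesis genes were higher in distal, 12 of 21, and 12 higher and 1 lower adjusted over the list alone (median 0.96, camera adjusted p = 7.09e-05, and adjusted p = 0.617 with an estimated correlation). B cell and plasma cell genes were higher in distal, 13 of 15 over all genes and adjusted over the list alone (median 3.18, camera adjusted p = 2.75e-07, and adjusted p = 0.485 with an estimated correlation). T cell and intraepithelial lymphocyte genes were lower, 13 of 17, and 14 adjusted over the list alone (median -2.65, camera adjusted p = 2.31e-09, and adjusted p = 0.485 with an estimated correlation), with Gzma, a granzyme, going from 11700 ± 5310 to 835 ± 280.

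The fourth comparison repeated the proximal to distal difference in cKO. The bile acid genes Slc10a2 (from 7.88 ± 2.48 to 1750 ± 274) and Fabp6 (from 7.05 ± 4.46 to 60300 ± 33200) were again higher in distal, and Akp3, Tmprss15 and Otop3 lower. Slc5a8 had 0 reads in the cKO proximal libraries and was at least 869-fold higher in distal against a floor of 3 reads per library. Fgf15, the ileal hormone that restrains bile acid synthesis, also had 0 reads in proximal and was at least 89.9-fold higher in distal. B cell genes, which were higher in distal in WT, did not pass in cKO (0 of 15 genes over all genes and adjusted over the list alone in limma, median -0.23, camera adjusted p = 0.7). In this comparison 1806 genes passed (limma, adjusted p under 0.05), 714 higher and 1092 lower in distal, 1367 of them by at least 2-fold (568 higher, 799 lower). This fit left the pairing out, and 2601 genes passed with the sample number as a block. The count of 1806 moved to 862 without both cKO libraries numbered 1, to 1031 without cKO proximal 1, to 1148 without cKO proximal 3 and to 2785 in DESeq2.

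By the naming rule the largest cKO differences upward were in Fabp6 (12.82, SE 1.07), Plb1 (11.07, SE 0.78), Slc5a8 (at least 869-fold, with 0 reads in proximal), the phosphate transporter gene Slc34a2 (8.03, SE 0.92), Tmigd1 (7.91, SE 0.54) and Slc10a2 (7.65, SE 0.37). The largest downward were in Akp3 (-9.73, SE 1.12), Reg1 (-9.26, SE 0.78), Tmprss15 (-9.14, SE 0.73), Sult6b2 (-8.99, SE 0.99), Slc16a9 (-8.66, SE 0.58) and Otop3 (-8.15, SE 0.59). Bmpr1a was 555 ± 98.7 in distal and 943 ± 130 in proximal cKO libraries (-0.77, adjusted p = 0.0202, and up to 0.0936 with 1 library left out, the call ending without cKO proximal 1, cKO proximal 3, cKO distal 1 or cKO distal 3). Of 48 proximal enterocyte genes 31 were lower in distal, and 37 adjusted over the list alone (median -1.56, camera adjusted p = 6.62e-24, and adjusted p = 0.305 with an estimated correlation). Of 38 distal enterocyte genes 24 were higher and 1 lower, and 29 higher and 1 lower adjusted over the list alone (median 2.1, camera adjusted p = 3.35e-24, and adjusted p = 0.305 with an estimated correlation). Bile acid genes were higher, 7 of 13 with 1 lower, and 8 higher and 1 lower adjusted over the list alone (median 1.26, camera adjusted p = 1.46e-05, and adjusted p = 0.305 with an estimated correlation). Cell cycle genes were higher, 11 of 38 with 1 lower, and 19 higher and 1 lower adjusted over the list alone (median 0.76, camera adjusted p = 5.12e-09, and adjusted p = 0.427 with an estimated correlation). Paneth cell genes were higher, 8 of 17, and 14 adjusted over the list alone (median 2.15, camera adjusted p = 9.4e-09, and adjusted p = 0.377 with an estimated correlation), with Defa21 going from 18.1 ± 13 to 2230 ± 1340. Fatty acid oxidation genes were lower, 10 of 26 with 1 higher, and 11 lower and 1 higher adjusted over the list alone (median -0.43, camera adjusted p = 1.16e-07, and adjusted p = 0.305 with an estimated correlation). T cell and intraepithelial lymphocyte genes were lower, 13 of 17, and all 17 adjusted over the list alone (median -1.59, camera adjusted p = 5.12e-09, and adjusted p = 0.427 with an estimated correlation). The MHC class II list did not pass (median 0.88, camera adjusted p = 0.212) but did with the sample number as a block (camera adjusted p = 0.000403, and adjusted p = 0.351 with an estimated correlation). The smooth muscle list of WT went from 0.0905 to 0.0483 in the same way (adjusted p = 0.477 with an estimated correlation).

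Genes called in the segment comparison of both genotypes numbered 415 higher and 804 lower in distal in both, where independent lists would share 84.68 and 133.5, and 10 had opposite directions. Slc10a2, Fabp6, Plb1 and Slc5a8 were higher and Akp3, Tmprss15, Reg1, Sult6b2 and Otop3 lower in distal in both genotypes. The fold changes correlated at r = 0.659 across genes. The count of 1219 became 762 without cKO proximal 1.

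The interaction asked whether the genotype effect differed between segments. Pyy fell more in proximal than in distal cKO libraries (-5.81 and -1.8, difference 4.02, SE 0.53, adjusted p = 0.0117). The nucleoside transporter gene Slc28a1 had log2 fold changes of -1.32 in proximal, which did not pass (adjusted p = 0.0699), and of 2.44 in distal (difference 3.76). Slc40a1 stood at 8480 ± 2190 in cKO and 12300 ± 709 in WT proximal libraries, and at 59.5 ± 20.2 and 578 ± 47.2 in distal ones (difference -2.76, SE 0.35, adjusted p = 0.0117). Ighg2b fell by 2.5 in proximal and by 8.77 in distal on the log2 scale (difference -6.27, SE 0.82). In all, 99 genes passed (limma, adjusted p under 0.05), 30 with a higher and 69 with a lower genotype effect in distal, and 460 passed with the sample number as a block, since the numbers pair the samples.

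Other genes with a higher effect in distal were Ces2b, a carboxylesterase (3.47), Acox2, a peroxisomal oxidase (2.94), the deacetylase gene Aadac (2.52) and the EGF receptor ligand gene Areg (2.5). Those with a lower effect in distal were Mfge8 (-3.37), Ighm (-3.3), the phosphatase gene Dusp2 (-3.19) and Gga2, a Golgi sorting adaptor (-2.82). Of these 12 genes, Pyy, Ighg2b and Slc40a1 alone stayed past the threshold in every fit without 1 library (highest adjusted p = 0.049 for each). Leaving out WT distal 2 ended the calls of Slc28a1, Ces2b, Acox2, Aadac, Areg, Mfge8, Ighm, Dusp2 and Gga2. The highest adjusted p without 1 library was 0.0555, 0.0735, 0.051, 0.124, 0.125, 0.0505, 0.119, 0.103 and 0.106 for these genes, and leaving out cKO distal 1 ended all of these calls but that of Mfge8. The count of 99 was 24, 32 and 192 without WT proximal 1, 2 and 3, 7 and 266 without WT distal 2 and 3 (the latter with 59% higher, against 30.3%), 28, 64 and 51 without cKO proximal 1, 2 and 3, and 9, 37 and 157 without cKO distal 1, 2 and 3. It was 2 without both cKO libraries numbered 1, with 0% higher, so the call of Pyy ended in that fit. The count was 58 and 168 with pseudocounts of 0.1 and 5. It was 595 in DESeq2, 20 with voom weights, and 62 and 59 in edgeR with DESeq2 size factors and without a count filter (45.2% and 49.2% higher).

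Proximal enterocyte genes had a median difference of 1.15, with 4 of 48 genes higher and 1 lower, and 18 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.18e-16, and adjusted p = 0.522 with an estimated correlation). Gstm6 (2.19), Aldh1a1 (1.81) and Ckb (2.43) passed with a higher effect in distal, and all 3 calls ended without WT distal 2 (highest adjusted p without 1 library 0.0505, 0.0539 and 0.0794, the last 2 without cKO distal 1). Cell cycle genes had a median of -0.94, with 0 of 38 passing in limma over all genes and 11 lower adjusted over the list alone (camera adjusted p = 3.13e-12, and adjusted p = 0.567 with an estimated correlation). B cell and plasma cell genes had a median of -3.18, with 2 of 15 lower, and 13 lower adjusted over the list alone (camera adjusted p = 5.11e-11, and adjusted p = 0.522 with an estimated correlation). Enteroendocrine genes had a median of 0.9, with 3 of 27 higher, and 4 adjusted over the list alone (camera adjusted p = 4.67e-07, and adjusted p = 0.567 with an estimated correlation). BMP-induced genes had a median of 0.67, that is a smaller fall in distal, with 0 of 11 passing in limma and 1 higher adjusted over the list alone (camera adjusted p = 0.00732, and adjusted p = 0.522 with an estimated correlation), a call that ended without cKO distal 3 (camera adjusted p = 0.0556). Id3 had a difference of 1.06 (adjusted p = 0.0689). By the fry test 0 of the 37 lists passed in the interaction.

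**Figure D3:**
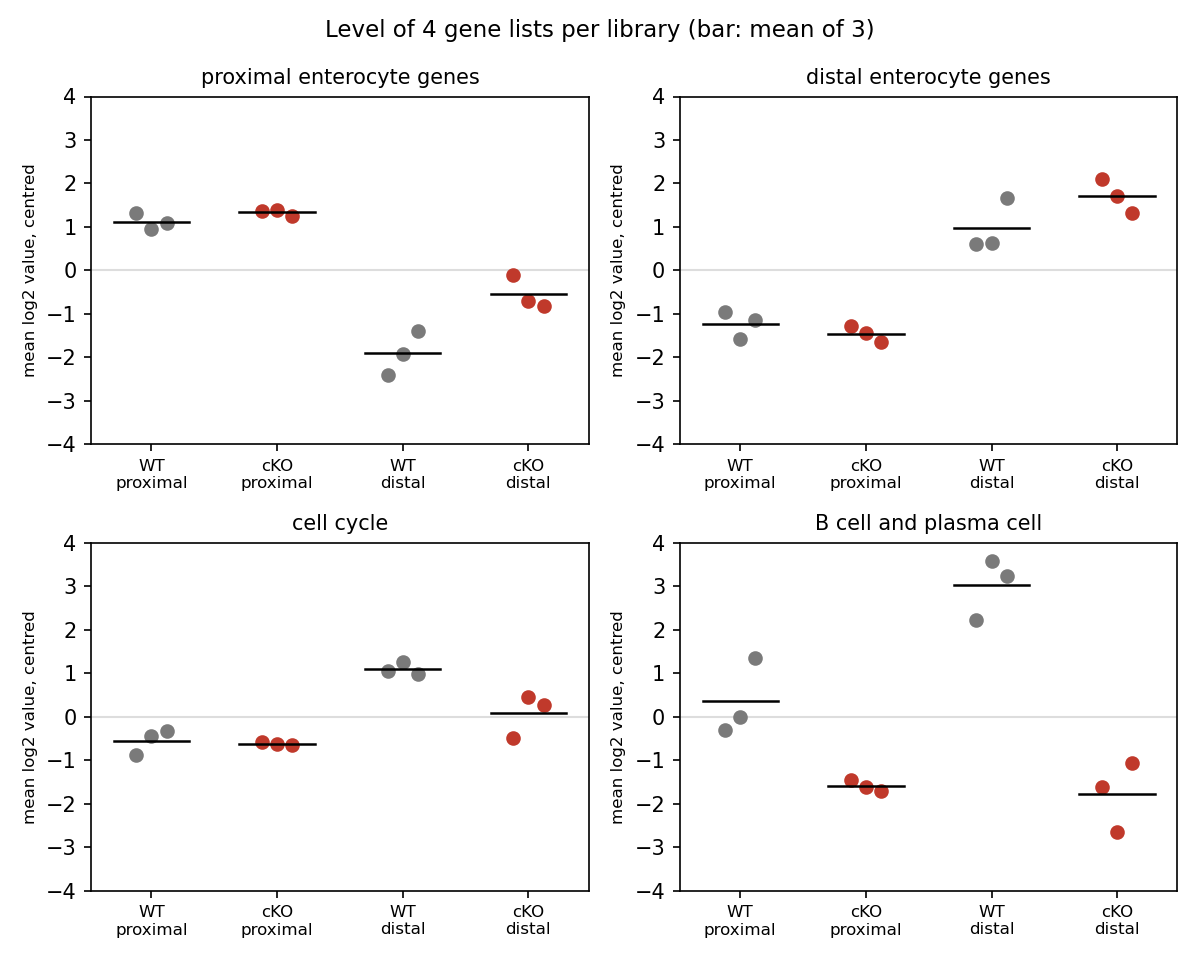
Level of 4 gene lists in the 12 libraries, as the mean log2 value of the list's genes after centring each gene over the libraries, with a point per library and a bar at the mean of the 3 libraries of a group. Proximal enterocyte genes of the cKO distal libraries lie between those of the WT distal and the proximal libraries, and B cell and plasma cell genes are highest in the WT distal libraries.

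The last comparison set the genotype effect, averaged over segments, against the segment effect, averaged over genotypes. Across the 17175 genes, which are not independent replicates, r was -0.187 and Spearman's rho -0.224. The WT distal libraries enter the segment effect with a plus sign and the genotype effect with a minus sign. Features of that group alone therefore push r towards negative values, so r does not show a general tendency. B cell and plasma cell genes had such a pattern. Their list median was 3.18 between WT segments, -5.21 between distal genotypes and -0.23 between cKO segments. How much of r came from such genes was not tested. Fabp1, Treh and Gstm6 were lower in distal WT libraries and higher in cKO than in WT distal libraries. They are examples of opposite signs, and Slc40a1 of the same sign. The WT distal libraries stand in both of these contrasts, so the examples share that limit. Among the 1219 genes called in the same direction between segments in both genotypes, 37.7% had the same sign in both effects. An exact permutation of the 6 numbered sample pairs between genotypes gave p = 0.1, which is the smallest that 10 divisions allow, and the largest absolute r among the other divisions was 0.172.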

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

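The tests of a lower non-epithelial share, of the place of dissection and of fewer crypt cells were chosen only after the results were seen. Groups of 3 libraries are too small for a test of single libraries that stand apart.

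The genes and lists of the next paragraphs differed between the 2 segments in the effect of genotype by the interaction test. It called 99 genes, and 7 of 100 assignments of genotype within the segments, the real one included, gave as many, with 5562 in the highest other. An exchange of the genotype names of all distal libraries puts the genotype effect itself into the interaction, so that value points to a structure of the samples, and chance was not excluded by this count. When the numbered pairs of libraries were kept together, 1 of 10 divisions gave as many and the highest other gave 0, which is too few divisions for a share under 0.05. For the other comparisons 1 of 10 divisions gave as many genes as the real one, again too few: the real counts were 1418, 4297, 4137 and 1806, and the highest others 0, 0, 1 and 0. In the other divisions of these sets of 10, the real difference falls partly within the groups and widens their spread. Their low counts are therefore no measure of what chance gives.

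The single genes with the largest differences of the genotype effect, distal minus proximal on the log2 scale, were Pyy (4.02), Slc28a1 (3.76), Ces2b (3.47), Acox2 (2.94), Aadac (2.52) and Areg (2.5), and in the other direction Ighg2b (-6.27), Mfge8 (-3.37), Ighm (-3.3), Dusp2 (-3.19), Gga2 (-2.82) and Slc40a1 (-2.76).

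None of the following lists passed with an estimated correlation (adjusted p = 0.522 to 0.74), nor did any pass by fry. The median difference was 1.15 for proximal enterocyte genes, 0.74 for distal enterocyte genes, 0.46 for brush border genes, 0.77 for fat absorption, 0.94 for sugar and peptide uptake, 0.5 for fatty acid oxidation, 1.2 for bile acid genes, 0.68 for goblet cell genes, 0.9 for enteroendocrine genes and 0.67 for BMP-induced genes. It was -0.94 for cell cycle genes, -1.09 for villus base antimicrobial genes, -3.18 for B cell and plasma cell genes, 0.86 for fibroblast and telocyte genes and 0.91 for T cell and intraepithelial lymphocyte genes. The BMP-induced call ended without cKO distal 3 (camera adjusted p = 0.0556), that of villus base genes without WT distal 1 or cKO distal 3 (up to 0.278), that of fibroblast genes without WT proximal 1, WT distal 3 or cKO distal 3 (up to 0.575), and that of T cell genes without WT proximal 2, WT proximal 3 or cKO proximal 2 (up to 0.108).

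The first pattern weighed is the rise of proximal enterocyte genes in cKO distal libraries. A lower share of non-epithelial cells would raise all enterocyte genes alike, but the proximal enterocyte list rose by 0.82 (SE 0.12) more than the brush border list, which argues against it as the whole cause. Tissue taken nearer to the proximal end would need the distal enterocyte list to change by -0.99, for a shift of 45.1% of the WT axis, and it changed by 0.74 (SE 0.42). With the mitochondrial share as a covariate the list median was 1.02 instead of 1.41 (camera adjusted p = 8.06e-09), and 13 instead of 34 of 48 members passed, which argues against that share as the whole cause. Each of these causes was weighed alone, and a mixture, such as a shifted site together with a change of cell composition, was not tested. The genotype itself and a part from cell composition, the place of dissection or the mitochondrial share stay open, and no test here decides between them.

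The second pattern is the lower level of cell cycle genes in cKO distal libraries (-1.02, SE 0.31). B cell follicles in the WT distal tissue could supply dividing cells (the B cell list differed by -4.79, SE 0.62), and with that list's level as a covariate the change was -0.73 (SE 0.83), so the 2 cannot be told apart in 12 libraries. Fewer crypt cells would lower stem and Paneth cell genes too: the stem cell list changed by 1.16 (SE 0.21) more than the cell cycle list, but 7 of its 20 genes rose and 3 fell. The Paneth cell list was lower by camera alone (median -1.3, camera adjusted p = 0.0463, and adjusted p = 0.771 with an estimated correlation), with 2 of 17 genes lower and 1 higher and 0 adjusted over the list alone, and the call ended in 4 fits without 1 distal library (up to 0.223) and with the mitochondrial share (0.761). Fewer crypt cells thus cannot be told apart from a change within them.

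The third pattern is the set of 162 genes (37 higher, 125 lower in cKO) that changed at least 4-fold in both segments. A stretch of another strain's genome around Bmpr1a would gather them there, but 1 of the 162 lies within 20 Mb, where 268 tested genes lie (odds ratio 0.39, Fisher p = 0.525). The count bears only on the set as a whole, which holds many immunoglobulin genes of other chromosomes. The 1 gene near Bmpr1a, Gm5460, is named outside the rule. It rose by 3.16 in proximal and 3.06 in distal on the log2 scale, and such a stretch stays open for it. Stretches elsewhere in the genome were not tested. Without the cKO libraries numbered 1, which lack Y-linked reads, 122 of 162 were still called in both segments and all 162 kept their direction in both, which argues against the sex of that sample as the cause of the set. For Eno1b, reads may have moved from its near-identical copy Eno1 (99.5% over 1652 of 1791 bases): in proximal Eno1b gained 2490 (SE 114) scaled reads while the sum of both genes changed by -2050 (SE 827), as such a move allows, and in distal the sum changed by 457 (SE 2240), too wide to tell. The genotype itself and stretches of another strain's genome elsewhere stay open for the other genes, and fewer lymphoid and myeloid cells only for those lower in cKO.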

How the results depend on the processing

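The mitochondrial covariate, the TMM factors, edgeR on recovered reads and the omission of both cKO libraries numbered 1 were chosen after seeing the data. No named gene that passed turned its direction in the settings run for named genes. The share of calls that were higher did cross 50% over the fits without a fold threshold. It lay between 39.7% and 57.4% in proximal (51% at first), 31.3% and 57.3% in distal (53%), 43.1% and 58% for the WT segments (49.2%) and 0% and 59% for the interaction (30.3%). With the 2-fold threshold 428 of 1084 proximal calls were higher. Of 438 named gene calls 433 stayed past the threshold with the replicate block, 318 with the mitochondrial covariate, 310 in every fit without 1 library, 400 of 431 in edgeR on recovered reads, 404 of 431 in edgeR with DESeq2 size factors and 430 of 434 in DESeq2. The genotype log2 fold change of Bmpr1a lay between -0.29 and 0.192 over all settings and never passed. The correlation of genotype and segment effects lay between -0.263 and -0.139. The filter set for scaled values removed 0 genes, so the alternative without it gave nothing to compare.

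Counts of genes moved by more than 1.5 times as follows, and the cause was not tested. With the mitochondrial covariate, 1418 became 292 in proximal, 4297 became 1356 in distal and their overlap of 928 became 135. The share differs by genotype, so the covariate also takes up part of the genotype effect. Without both cKO libraries numbered 1, which leaves fewer samples, the counts were 766 in proximal, 2160 in distal, 862 for the cKO segments, 2 for the interaction and 460 for the overlap of genotype calls. In DESeq2 they were 2322 in proximal, 2785 for the cKO segments, 595 for the interaction and 1545 for that overlap. The interaction count of 99 was 58 and 168 with pseudocounts of 0.1 and 5, 62 in edgeR with DESeq2 size factors, 59 without a low count filter, and 20 in limma voom. The number of lists that passed (14, 16, 18, 25 and 15 of 37) was 0 in all 5 comparisons with an estimated correlation. With the mitochondrial covariate the Paneth cell, sugar and peptide and mitochondrially encoded lists no longer passed in proximal (camera adjusted p = 0.642, 0.85 and 0.273), nor the brush border, Paneth cell, distal enterocyte, myeloid and mitochondrially encoded lists in distal (0.998, 0.761, 0.481, 0.338 and 0.86). With fry the number was 6 in proximal, 9 in distal, 10 for the cKO segments and 0 for the interaction.

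Fits without 1 library gave 580 (cKO proximal 2) to 1360 genes (WT proximal 1) in proximal, 2466 (cKO distal 1) to 4954 (WT distal 3) in distal, 2741 (WT distal 2) to 3924 (WT distal 3) for the WT segments, 1031 (cKO proximal 1) to 1545 (cKO distal 1) for the cKO segments and 7 (WT distal 2) to 266 (WT distal 3) for the interaction. The overlap of genotype calls was 398 (without cKO proximal 2) to 1133 (without cKO distal 3), and that of segment calls 762 (without cKO proximal 1) to 1198 (without WT proximal 1).

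With the replicate block the interaction count was 460, and the pairing moved no other count by more than 1.5 times (4935 and 2601 for the WT and cKO segments). It brought smooth muscle in WT and MHC class II in cKO past the threshold between segments and changed no other list call there. Between genotypes the numbers do not pair the samples (correlations -0.15, -0.081 and -0.11 in proximal and -0.1, 0.049 and -0.12 in distal), and the block gave 1388 and 4242 genes.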

Other observations

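Several groups not described above held changed members without passing as lists by camera. Among BMP ligands, receptors and antagonists in the distal segment 6 of 22 genes were higher and 1 lower in cKO, and 8 higher and 1 lower adjusted over the list alone (median 0.44, camera adjusted p = 0.101, and adjusted p = 0.647 with an estimated correlation). By the fry test this list did pass (fry adjusted p = 0.0169). Besides Bmp3, Bmp2 rose from 521 ± 127 to 1520 ± 304, Bmp4 from 13.9 ± 4.04 to 82.7 ± 45.6 and the receptor gene Acvr2a from 259 ± 67.4 to 507 ± 51.1. In the Notch list 5 of 17 genes rose and 6 fell, and 5 rose and 7 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.34). The ligand genes Dll1 (from 171 ± 78.6 to 699 ± 176) and Jag1 (from 53.9 ± 24 to 231 ± 111) rose. Notch2 (from 540 ± 184 to 137 ± 48.8) and Mfng (from 185 ± 73.5 to 26.8 ± 6.19) fell. B cell and plasma cell genes fell in the same comparison (list median -5.21), and whether Notch2 and Mfng fell along with them was not tested. In the stem cell list 4 of 20 rose and 4 fell in proximal, and 7 rose and 3 fell in distal, with the same counts adjusted over the list alone (medians -0.05 and -0.2, camera adjusted p = 0.674 and 0.719). Smoc2 and Lrig1 rose in both segments, in proximal from 62.4 ± 32.3 to 298 ± 66.3 and from 159 ± 38.6 to 504 ± 48.3. The transcription factor gene Ascl2, named after its values were seen, fell in both (log2 fold changes -2.55 in proximal and -2.15 in distal).

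Between segments, interferon-stimulated genes were lower in distal, 10 of 23 in WT and 11 of 23 in cKO, and 11 and 20 adjusted over the list alone (medians -0.96 and -1.62, camera adjusted p = 0.000232 and 1.16e-07, and adjusted p = 0.693 and 0.427 with an estimated correlation). Rtp4 was 584 ± 317 in proximal and 141 ± 37.8 in distal WT libraries. Stomach and Brunner gland genes were lower in distal, 5 of 8 in WT and 3 of 8 in cKO, and 6 and 5 adjusted over the list alone (medians -4.7 and -3.78, camera adjusted p = 0.00206 and 0.00039, and adjusted p = 0.485 and 0.305 with an estimated correlation). The level of this list (mean centred log2 value) was -0.61 in WT proximal 1, against 2.77 and 3.46 in WT proximal 2 and 3. Pgc and Tff2 had 0 reads in WT distal libraries and were at least 22.3-fold and 33.5-fold lower there than in proximal, against a floor of 3 reads per library. Villus base antimicrobial genes were higher in distal WT libraries, 9 of 15 with 2 lower, and 9 higher and 3 lower adjusted over the list alone (median 4.2, camera adjusted p = 0.00796, and adjusted p = 0.693 with an estimated correlation). Duox2 stood at 2300 ± 951 there and Nos2 at 2410 ± 252, against 35.3 ± 24.1 and 22.9 ± 6.51 in proximal.

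Some list calls depended on single libraries. In proximal, the sugar and peptide list (median 0.44, camera adjusted p = 0.0175, and adjusted p = 0.86 with an estimated correlation) ended without WT proximal 2 (0.128) and with the mitochondrial share as a covariate (0.85). The MHC class II list (median -1.21, 0.0112, and 0.593 with an estimated correlation) ended without cKO proximal 3 (0.189). In distal, the brush border list (median 0.36, 0.0301, and 0.771 with an estimated correlation) ended without WT distal 1, WT distal 2, cKO distal 1 or cKO distal 2 (up to 0.146), without both cKO libraries numbered 1 (0.137) and with the mitochondrial share (0.998). By fry the sugar and peptide, MHC class II and brush border lists did not pass in these comparisons (fry adjusted p = 0.442, 0.308 and 0.167).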
